A study of Homo sapiens with 64 samples.

How the data were processed

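Total RNA of human breast cell lines kept at 1% O2 for 24 h or at 20% O2 was enriched for mRNA, made into stranded libraries with 12 PCR cycles and sequenced as 150 bp paired reads, per the labels. The authors deposited estimated gene counts (expected counts, not normalized for library size) from Salmon 0.8.2, and the submitters' notes name the builds hg19 and GRCh37. How transcripts were summed to gene symbols, and which annotation was used, is not stated. The table identifies genes by symbol alone, with 56470 symbols and 62 sample columns, all used. The reference annotation at hand is on GRCh38, so no positions are given, and it served only to look up older symbols. Between 22.5% and 37.3% of the values in a library were not whole, and all were rounded to the nearest whole number (tolerance 0.5). The highest share of equal counts between any 2 libraries was 1.91% of genes.

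The labels list 64 samples of 32 lines; the 2 samples of HCC1954 were not analysed here, which leaves 31 lines and 5 Basal A lines in place of 6. Columns were matched to labels by line name and O2 level. The columns named HME were read as the line HME2, since the other label that holds HME, htert-HME, has columns of its own, and those named MDA-MB-231 as MDA-MB-231-PSOC, since no other label holds that name. The subtype of each line is as the labels give it.

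Genes were kept by filterByExpr on subtype and O2 level, which left 19293 genes holding 97.8% to 99.9% of the counts of each library. Library totals ranged from 2996008 to 21650280 counts, with a median of 8960446. Normalization used TMM, and tests used the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. For the effect of O2 over all lines the model held a coefficient per line and 1 for O2. For effects within subtypes and their differences it held a coefficient per line and an O2 coefficient for each subtype, in 1 fit over all 62 libraries. Subtypes at 20% O2 were compared over 28 libraries without a block. SE values are the absolute log2 fold change divided by the square root of F. Levels per library are log2 CPM with a prior count of 2.

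For gene groups, 35 lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives, and members were also counted adjusted over the list alone. Each list needed 3 tested members. Correlations and differences of the response index used SciPy 1.17.1 with exact or 100000-fold permutation, and figures were drawn with matplotlib 3.10.9 under Python 3.11.15 and NumPy 2.4.6. Permutation tests were two-sided.

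The comparisons, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 genes with the largest rise and the 8 with the largest fall over all lines among those past the threshold, with an average log2 CPM of at least 1 and the same sign in at least 29 lines. It also took up to 4 members of each list with the smallest p, the response index genes, HIF1A and EPAS1. For each subtype difference and for Normal lines it took up to 5 genes each way past the threshold and above that level, or the gene with the smallest p. For subtypes at 20% O2 it took up to 4 members of the luminal, basal and mesenchymal lists and up to 5 genes each way. Genes with a change of at least 1.5-fold in every line were to be named, and 0 met that part. The text gives those of the 20% O2 genes that belong to the 3 lists, together with CA12.

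Alternatives were size factors of DESeq2 1.42.0 in edgeR, no filter, the DESeq2 Wald test, limma-voom, no line block, minimum folds, other prior counts, each subtype fitted alone, each line or Basal A or Normal line left out in turn, models without Normal and Unknown lines and without MCF10A, MCF12A and HBL100, and the glycolysis list in place of the index genes. Leaving out SUM149 and SUM159, leaving out Basal A lines in turn, the older quasi-likelihood fit with estimateDisp, and the list tests without Normal, Unknown and non-carcinoma lines were chosen after the data were seen. The fit without MCF10A, MCF12A and HBL100 was planned for the differences between subtypes, and its values within subtypes were added later. The tests were tried on simulated data with the same depths, where for O2 effects the dispersion was the same for all genes. Changed genes were drawn from those above a minimum mean count, and their response varied between lines less than the response index did. Unchanged genes had no spread of response beyond that dispersion. The rates hold for that setting: real genes that vary more may be found less often, and unchanged ones may pass more often. Over all lines 94.0% of genes with a 1.5-fold change were found, within Luminal 31.3%, within Basal A 17.9% and within Normal 2.99%, and at most 0.0471% of unchanged genes passed.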

Results

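RNA sequencing measured gene expression in 31 human breast cell lines, each kept at 1% O2 for 24 h (hypoxia) or at 20% O2 (normoxia), which is 62 libraries with 1 library per line and O2 level. The labels place 9 lines in the Luminal subtype, whose cells resemble hormone-responsive ductal cells, 5 in Basal A and 14 in Basal B, the basal-like and more mesenchymal subtypes. A further 2 lines, HME2 and htert-HME, are called Normal, and DU4475 is called Unknown. The labels also list HCC1954 at both O2 levels, and its 2 samples were not analysed here. Total counts ranged from 2996008 to 20044846 per hypoxic library (median 8315787) and from 3335058 to 21650280 per normoxic library (median 9220332). Mitochondrially encoded genes held 2.00% to 16.1% of the counts in hypoxia (median 6.62%) and 2.21% to 17.8% in normoxia (median 7.94%). For 58 of the 62 libraries, the closest library was the other library of the same line. The exceptions were the 4 libraries of SUM149 and SUM159, so the counts of genes that passed are also given without these lines.

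The main comparison asked which genes changed at 1% O2 across all 31 lines. CA9, which encodes the membrane enzyme carbonic anhydrase IX, rose most among genes with an average log2 CPM of at least 1 and the same sign in at least 29 lines, with a log2 fold change of 4.54 ± 0.27 (SE throughout for fold changes; adjusted p = 8.40e-14), and was higher in 30 of 31 lines. NDRG1, a stress-response gene, rose by 3.30 ± 0.37 (adjusted p = 1.42e-07) and PPFIA4 by 3.20 ± 0.30 (adjusted p = 5.64e-09), each in 31 of 31 lines. The HIF prolyl hydroxylase EGLN3 rose by 2.58 ± 0.31, MIR210HG, the host transcript of microRNA 210, by 2.51 ± 0.21, and the secreted hormone STC1 by 2.44 ± 0.30. ANKRD37 rose by 2.44 ± 0.35 and PFKFB4, which sets fructose 2,6-bisphosphate levels, by 2.11 ± 0.22. Within that set, the largest falls were smaller than these rises. MPV17L2 changed by −0.61 ± 0.12 (adjusted p = 2.73e-04), the tRNA thiolation gene CTU2 by −0.58 ± 0.08 (adjusted p = 3.36e-06), DAGLA by −0.54 ± 0.09 and AUNIP by −0.54 ± 0.09. The antioxidant genes NQO1 (−0.53 ± 0.06, adjusted p = 2.87e-08) and SRXN1 (−0.53 ± 0.08, adjusted p = 5.23e-06) were each lower in 30 of 31 lines, and ASB13 (−0.51 ± 0.11) and NUFIP1 (−0.47 ± 0.09) also fell. Messenger RNA of HIF1A did not pass the test (−0.10 ± 0.07, adjusted p = 0.362), whereas EPAS1, which encodes HIF-2 alpha, fell by 0.23 ± 0.06 on the log2 scale (adjusted p = 0.00551) and was lower in 26 lines.

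Of 19293 genes tested, 2201 were higher and 2327 lower at 1% O2, and 564 and 71 of these changed at least 1.5-fold. Which direction held more genes was not settled: more were higher with size factors (2589 against 1915), with DESeq2 (2334 against 2024), without SUM149 and SUM159 (1673 against 1641), and when SUM185 alone (2311 against 2146) or some other single lines were left out. After SUM149 and SUM159 were left out, 3314 genes passed in place of 4528, and 3236 genes were in both sets. With line left out of the model as a block, 111 genes passed. The p-values of single genes measure the spread between lines, since no line had a repeated library. Those of camera with the preset correlation, given below for lists, rest on the spread between genes.

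**Figure D1:**
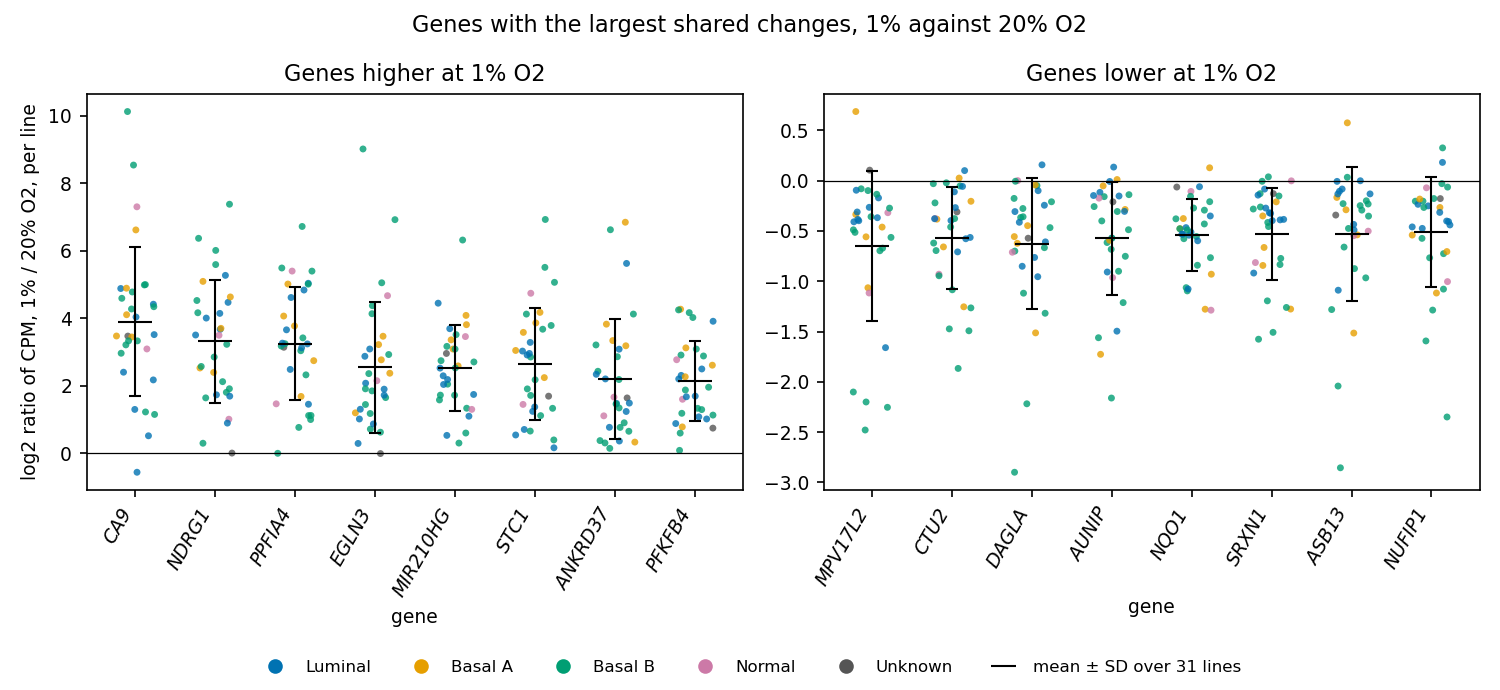
Log2 ratio of 1% to 20% O2 in each of the 31 lines (points, coloured by subtype) for the 8 genes with the largest rise and the 8 with the largest fall under the naming rule, with the mean and SD over lines. CA9 has the largest fitted rise (4.54) and MPV17L2 the largest fitted fall (−0.61).

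Genes of sugar use rose together. Of 23 glycolysis and glucose transport genes, 22 rose and 1 fell, over all genes tested and adjusted over the list alone (camera adjusted p = 2.73e-38). LDHA, which makes lactate from pyruvate, rose by 1.47 ± 0.10, the glycolytic kinase PGK1 by 1.48 ± 0.11, TPI1 by 0.88 ± 0.08 and pyruvate kinase PKM by 0.67 ± 0.06, and the glucose transporter SLC2A1 rose by 1.29 ± 0.17. In glycogen metabolism 9 of 14 members rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 3.89e-07). These included PPP1R3G (2.02 ± 0.23), the branching enzyme GBE1 (1.17 ± 0.14), PGM1 (0.75 ± 0.08) and glycogen synthase GYS1 (0.59 ± 0.08). Among 9 genes of pH regulation, 6 rose and 1 fell, or 6 and 2 adjusted over the list alone (adjusted p = 0.00108), with the lactate exporter SLC16A3 at 0.91 ± 0.14, CA12 at 0.60 ± 0.16 and the proton exchanger SLC9A1 at 0.18 ± 0.06. The lipid storage list was not called (adjusted p = 0.152). Of its 15 members 5 rose and 2 fell, also adjusted over the list alone, among them the lipid droplet genes HILPDA (1.38 ± 0.31), PLIN2 (0.80 ± 0.22) and PLIN3 (0.19 ± 0.05), while the triglyceride enzyme DGAT2 changed by −0.33 ± 0.09.

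Lists of oxygen sensing, secreted factors and collagen enzymes were called up. In the HIF pathway list 8 of 16 members rose and 1 fell, also adjusted over the list alone (adjusted p = 3.51e-04); EGLN1 rose by 1.16 ± 0.10, the transcription factor BHLHE40 by 1.26 ± 0.15 and CITED2 by 0.99 ± 0.13. Of 24 chromatin and RNA oxygenases that use 2-oxoglutarate, 12 rose and 3 fell, or 13 and 3 adjusted over the list alone (adjusted p = 1.78e-04). The histone demethylases KDM3A, KDM4B and KDM4C rose by 1.31 ± 0.14, 0.76 ± 0.08 and 0.50 ± 0.06, and the RNA demethylase ALKBH5 by 0.51 ± 0.08. Angiogenic and secreted factors rose in 14 of 19 members with 0 falls, or 14 and 1 adjusted over the list alone (adjusted p = 4.32e-11), including ANGPTL4 (2.66 ± 0.39), adrenomedullin ADM (1.92 ± 0.36), VEGFA (1.45 ± 0.18) and FGF11 (1.36 ± 0.13). Of 16 collagen modification genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 7.22e-09), with the crosslinking enzyme LOX at 2.12 ± 0.29, the collagen hydroxylases P4HA1 at 1.86 ± 0.19 and P4HA2 at 0.95 ± 0.12, and PLOD2 at 1.21 ± 0.16. In the mitophagy and hypoxia stress list 15 of 20 members rose and 1 fell, or 16 and 2 adjusted over the list alone (adjusted p = 6.68e-20), led by the mitophagy receptors BNIP3 (2.07 ± 0.18) and BNIP3L (1.60 ± 0.15), with adenylate kinase AK4 at 1.25 ± 0.12. The members that fell in these lists, apart from EPAS1, were picked out after their values were seen. They were the phosphofructokinase gene PFKM (−0.20 ± 0.05), SLC4A7 (−0.20 ± 0.07), PHF8 (−0.20 ± 0.05), RIOX2 (−0.40 ± 0.11), RIOX1 (−0.47 ± 0.16), LOXL3 (−0.26 ± 0.10) and SQSTM1 (−0.17 ± 0.05).

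The tumour hypoxia metagene, a published list of genes that rise in hypoxic tumours, had 28 of 51 members up and 6 down, or 30 and 7 adjusted over the list alone (adjusted p = 5.84e-15). All 10 genes of the response index, drawn from the lists above, rose, also adjusted over the list alone (adjusted p = 1.40e-25, median log2 fold change 1.89). In the metallothionein and metal handling list 6 of 16 members rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.00224). They included the copper-binding ferroxidase ceruloplasmin CP (1.58 ± 0.18), the iron carrier transferrin TF (1.04 ± 0.17), and the metallothioneins MT1X (0.87 ± 0.15) and MT1F (0.61 ± 0.13).

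All 3 lists of mitochondrial energy genes were called down. Of 38 nuclear genes of oxidative phosphorylation 12 fell and 0 rose, also adjusted over the list alone (adjusted p = 1.58e-04). That call was lost at an adjusted p = 0.396 with an estimated correlation and at 0.0518 with fry, and with size factors 5 of the 38 fell. CYCS, which encodes cytochrome c, changed by −0.40 ± 0.09, ATP5G1 by −0.29 ± 0.07, UQCRFS1 by −0.25 ± 0.06 and CYC1 by −0.21 ± 0.05. Of 13 mitochondrially encoded mRNAs 5 fell and 0 rose, or 7 fell adjusted over the list alone (adjusted p = 4.66e-04, but adjusted p = 0.364 with an estimated correlation and 0.0504 with fry), with MT-ND2 at −0.41 ± 0.11, MT-ND1 at −0.38 ± 0.10, MT-CO3 at −0.36 ± 0.12 and MT-CO2 at −0.31 ± 0.09. The fall was uneven over lines, as the mean log2 ratio of these mRNAs ran from −2.07 in HCC1569 to 0.39 in CAMA1. The share of counts in mitochondrially encoded genes had a median of 6.62% in hypoxia and 7.94% in normoxia. Of 22 tricarboxylic acid cycle genes 9 fell and 0 rose, or 10 fell adjusted over the list alone (adjusted p = 3.51e-04, but adjusted p = 0.138 with an estimated correlation), including IDH3A (−0.38 ± 0.07), ACO2 (−0.20 ± 0.04), PDHA1 (−0.16 ± 0.04) and DLST (−0.15 ± 0.04).

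Among lists of growth and replication genes 3 were called down. Ribosome biogenesis, the making of ribosomes in the nucleolus, had 22 of 28 members down and 0 up, or 24 down adjusted over the list alone (adjusted p = 2.32e-13, but adjusted p = 0.119 with an estimated correlation); RRP9 changed by −0.53 ± 0.09, NOP16 by −0.51 ± 0.11, BOP1 by −0.37 ± 0.06 and UTP4 by −0.32 ± 0.07. Of 38 DNA replication genes 23 fell and 0 rose, or 26 fell adjusted over the list alone (adjusted p = 3.26e-09, but adjusted p = 0.224 with an estimated correlation). Examples were the S-phase regulator E2F2 (−0.46 ± 0.10), the replicative helicase component CDC45 (−0.34 ± 0.07), RFC3 (−0.33 ± 0.07) and CHAF1B (−0.27 ± 0.06). Among 29 homologous recombination and mismatch repair genes 10 fell and 1 rose, or 14 and 1 adjusted over the list alone (adjusted p = 1.86e-04, but adjusted p = 0.292 with an estimated correlation). FANCA (−0.27 ± 0.07), XRCC3 (−0.25 ± 0.06) and FANCD2 (−0.19 ± 0.05) fell, and MSH3 rose by 0.19 ± 0.05. The mitosis list was not called (adjusted p = 0.163): HMMR (0.20 ± 0.06), ANLN (0.28 ± 0.10), KIF20A (0.16 ± 0.06) and TOP2A (0.18 ± 0.07) were the 4 of 30 members that rose, and 0 passed adjusted over the list alone. Ribosomal protein genes were called up (adjusted p = 1.19e-05, but adjusted p = 0.461 with an estimated correlation and 0.0742 with fry), with 3 of 40 members up, RPS9 (0.17 ± 0.06), RPL11 (0.14 ± 0.05) and RPS28 (0.13 ± 0.05), and 0 adjusted over the list alone. Replication-dependent histone genes had 9 of 17 members up and 0 down, also adjusted over the list alone (adjusted p = 4.76e-04, but adjusted p = 0.183 with an estimated correlation), including HIST1H1C (0.53 ± 0.15), HIST1H2AC (0.49 ± 0.11), HIST1H2BG (0.48 ± 0.14) and HIST1H3H (0.38 ± 0.10).

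Apart from the cholesterol and heat shock lists, the stress and inflammatory lists had members that passed in both directions. In the unfolded protein and integrated stress list (adjusted p = 0.660) 5 of 26 members rose and 4 fell, or 6 and 8 adjusted over the list alone. VLDLR rose by 1.42 ± 0.18 and HERPUD1 by 0.36 ± 0.08, while the cystine transporter SLC7A11 changed by −0.72 ± 0.15 and asparagine synthetase ASNS by −0.55 ± 0.12. Of 25 cholesterol synthesis genes 7 rose and 0 fell, or 8 rose adjusted over the list alone (adjusted p = 2.74e-04, but adjusted p = 0.347 with an estimated correlation), including STARD4 (0.61 ± 0.12), HSD17B7 (0.29 ± 0.07), LSS (0.21 ± 0.05) and SREBF2 (0.16 ± 0.04). Interferon stimulated genes (adjusted p = 0.951) had 3 of 34 up and 3 down, or 2 and 2 adjusted over the list alone, and the list's median lay below 0 while its mean and test lay above. IFI27 (0.38 ± 0.10) and IRF9 (0.35 ± 0.09) rose and IFI35 (−0.25 ± 0.08) and STAT1 (−0.22 ± 0.05) fell. Of 25 NF-kB and inflammatory genes (adjusted p = 0.138) 3 rose and 4 fell, or 3 and 6 adjusted over the list alone; PTGS2 rose by 0.50 ± 0.14, and the cytokine genes CXCL1, CSF3 and IL1B changed by −0.56 ± 0.14, −0.53 ± 0.17 and −0.41 ± 0.15. This list was called down without SUM149 and SUM159 (adjusted p = 0.0129, but adjusted p = 0.323 with an estimated correlation). In the immune evasion list 5 of 20 members rose and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.0415, but adjusted p = 0.339 with an estimated correlation), with LGALS1 (0.59 ± 0.12), the adenosine-producing enzyme NT5E (0.50 ± 0.12) and HLA-C (0.23 ± 0.08) up and the peptide transporter TAP2 (−0.44 ± 0.06) down. Among 18 immediate early genes 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0444, but adjusted p = 0.372 with an estimated correlation), with FOS at 1.23 ± 0.27, JUN at 0.56 ± 0.13, KLF6 at 0.54 ± 0.11 and EGR3 at −0.58 ± 0.19. The immune evasion and immediate early calls also ended with size factors (adjusted p = 0.0653 and 0.0707) and without SUM149 and SUM159 (adjusted p = 0.0783 and 0.149). Heat shock genes were not called (adjusted p = 0.612), with a median below and a mean above 0; HSPE1 (−0.25 ± 0.07) and HSP90AA1 (−0.17 ± 0.06) were the 2 of 16 that fell, also adjusted over the list alone. Only 1 fell with size factors, without SUM149 and SUM159, or without Normal, Unknown and non-carcinoma lines.

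Of 4 lists of breast cell identity 3 were called up. In the mesenchymal and claudin-low list 14 of 23 members rose and 0 fell, or 15 rose adjusted over the list alone (adjusted p = 2.37e-09), with CAV1 at 0.49 ± 0.10 and FBN1 at 0.33 ± 0.07. Basal keratinocyte genes had 9 of 23 members up and 0 down, or 10 and 1 adjusted over the list alone (adjusted p = 1.66e-05), including EGFR (0.63 ± 0.13), COL17A1 (0.62 ± 0.13), the laminin receptor subunit ITGB4 (0.58 ± 0.09) and TRIM29 (0.44 ± 0.09). Of 24 genes of epithelial to mesenchymal transition 7 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.00571, but adjusted p = 0.113 with an estimated correlation). ITGA5 (0.81 ± 0.17), VIM (0.78 ± 0.16) and FN1 (0.54 ± 0.13) rose and TWIST2 (−0.32 ± 0.09) fell. That list holds epithelial genes, such as CDH1 and EPCAM, beside mesenchymal ones, so its call up does not show a shift towards either state. It also shares members, among them VIM and FN1, with the mesenchymal list, so the calls of these lists are not independent. The mesenchymal list further holds LOX and NT5E, which were counted above in the collagen and immune evasion lists. The luminal list was not called (adjusted p = 0.275), with 6 of 22 up and 1 down, also adjusted over the list alone, among them the keratins KRT19 (0.64 ± 0.13) and KRT8 (0.32 ± 0.08), TFF3 (0.42 ± 0.11) and TBX3 (0.23 ± 0.06). Of the lists for other cell types, none was called by camera. CSF1R (0.95 ± 0.19) was the 1 of 6 leukocyte genes that rose, or 2 adjusted over the list alone, and that list was not called. KDR (0.97 ± 0.27), FAP (0.39 ± 0.14) and COL1A1 (0.30 ± 0.10) were the 3 of 16 fibroblast and endothelial genes that rose, also adjusted over the list alone (adjusted p = 0.110). Among 11 neural genes 3 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.153), with the enolase ENO2 at 1.64 ± 0.26, NEFL at 0.74 ± 0.18, TUBB3 at 0.49 ± 0.10 and MBP at −0.30 ± 0.10. ENO2 is also a member of the glycolysis list. With fry, which asks whether a list's own genes move on balance one way, the fibroblast, lipid and neural lists passed (adjusted p = 0.0233, 0.0104 and 3.47e-04). The lists that camera called also passed with fry, in the same direction, apart from oxidative phosphorylation, mitochondrially encoded mRNAs and ribosomal proteins. Adjusted p with fry was 3.90e-04 for ribosome biogenesis, 0.00529 for DNA replication and 0.0131 for recombination and repair. It was 3.47e-04 for the tricarboxylic acid cycle, 0.00120 for histones, 0.0262 for cholesterol synthesis and 1.96e-04 for epithelial to mesenchymal transition.

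Of the 35 lists, camera with its preset correlation called 19 up and 6 down, and 13 up and 0 down with an estimated correlation. Each called list without a value for the estimated correlation above passed there too, with adjusted p from 0.00394 to 0.0415. Of these 13 calls 5 ended when size factors replaced TMM, namely the HIF pathway, basal keratinocyte, metallothionein and metagene lists (each adjusted p = 0.0558 with an estimated correlation) and the mesenchymal list (adjusted p = 0.0742 with an estimated correlation). The mesenchymal call also ended without SUM149 and SUM159 (adjusted p = 0.0571 with an estimated correlation). With size factors in place of TMM, the interferon list, which was not called, changed its test direction from up to down and its median to above 0, and no other list changed direction. Members that rose without SUM149 and SUM159 numbered 9 in the mesenchymal list, 4 in the epithelial to mesenchymal list, 3 each in the pH, immune evasion and immediate early lists, 1 each in the mitosis, NF-kB and fibroblast lists and 0 among ribosomal proteins. The members that fell then numbered 4 in the recombination and repair list and 3 among mitochondrially encoded mRNAs. Without the Normal and Unknown lines, MCF10A, MCF12A and HBL100, none of the 35 list calls changed, but the unfolded protein list, which was not called, changed its test direction. Members that rose then numbered 2 in the pH list, 3 each in the epithelial to mesenchymal, immune evasion and immediate early lists, 4 in the cholesterol list and 2 in the mitosis list. Members that fell then numbered 7 in oxidative phosphorylation, 5 in recombination and repair, 2 among mitochondrially encoded mRNAs, 7 in the unfolded protein list and 0 in the NF-kB list. The median log2 fold change of all genes was 0.01 with TMM and 0.03 with size factors.

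**Figure D2:**
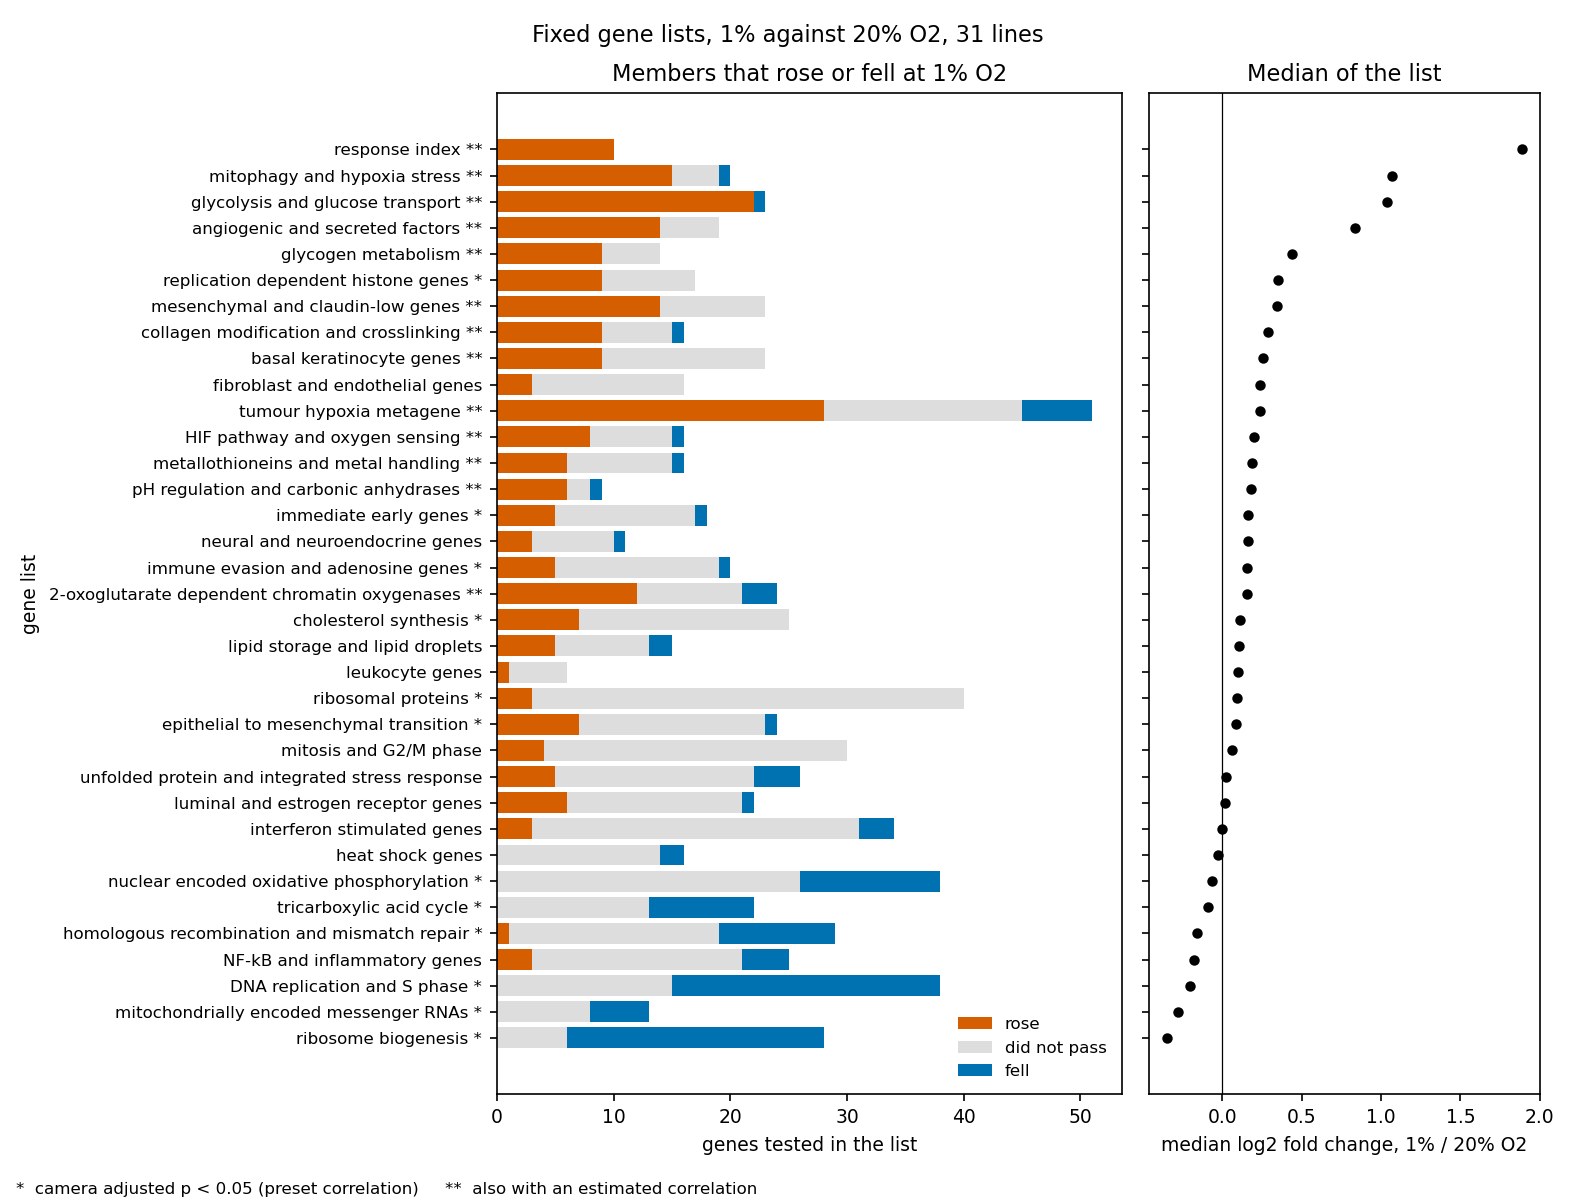
Members of each of the 35 gene lists that rose, fell or did not pass at 1% O2 (stacked bars, genes) and the median log2 fold change of each list (points), with 1 asterisk for a camera call and 2 for a call that held with an estimated correlation. Of 23 glycolysis genes 22 rose, and of 28 ribosome biogenesis genes 22 fell.

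The series title asks for a consensus across lines, so lines sharing each change were counted. At 1% O2, 38 genes were higher in every 1 of the 31 lines and 2, FARSB and SNAPC5, were lower. These 40 symbols were listed after their values were seen unless the naming rule held them. The 38 included the glycolytic genes ALDOA, ENO1, GAPDH, GPI, HK2, LDHA, PFKFB3, PFKFB4, PGAM1, PGK1, PKM and TPI1. They also held the oxygen sensor EGLN1, the demethylases KDM3A and KDM4B, and the collagen enzymes P4HA1 and PLOD2. The others were ANKRD37, ANKZF1, BNIP3L, C4orf3, CCNG2, DDIT4, ERO1A, FUT11, GBE1, MIR210HG, NARF, NDRG1, PDK1, PPFIA4, S100A10, SCD, SLC2A1, STC1, TCAF2, VLDLR and YEATS2. For LDHA the lowest line still had a log2 ratio of 0.41, and for PPFIA4 the ratios ran from 0.0041 to 6.72. At a threshold of 1.5-fold, 0 genes passed in every line, and 45 were higher and 0 lower in at least 24 lines. With a threshold of 2-fold this number was 13, and without SUM149 and SUM159 it was 31. In 100 random swaps of the O2 labels within lines, no swap gave a gene higher in every line, lower in every line, or at least 1.5-fold higher in at least 24 lines (highest number 0 for each).

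Within subtypes, the glycolytic response appeared in Luminal, Basal A and Basal B lines. LDHA rose by 1.64 ± 0.18 in the 9 Luminal lines, by 1.69 ± 0.24 in the 5 Basal A lines and by 1.31 ± 0.15 in the 14 Basal B lines. CA9 rose by 4.17 ± 0.86, 4.28 ± 0.66 and 4.66 ± 0.38, and BNIP3 by 1.78 ± 0.33, 2.58 ± 0.45 and 2.11 ± 0.26 in the same order. Of 23 glycolysis genes 14, 18 and 22 rose (adjusted p = 8.52e-39, 1.34e-40 and 1.04e-25), calls that held with an estimated correlation. VEGFA passed in Basal A (1.97 ± 0.46) and Basal B (1.26 ± 0.28) and had 1.41 ± 0.34 in Luminal lines (adjusted p = 0.0540). In Basal B lines basal keratinocyte genes (11 up, adjusted p = 2.76e-06) and mesenchymal genes (12 up, adjusted p = 1.48e-09) were called, also with an estimated correlation (adjusted p = 0.0327 and 0.0375). Cholesterol synthesis was called in Basal A (adjusted p = 9.78e-12), also with an estimated correlation (0.00762), though 1 of its genes rose.

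At the level of all genes, 93 were higher and 18 lower in Luminal lines, 143 and 8 in Basal A, and 1938 and 1678 in Basal B. In Basal B the balance turned to 1191 higher and 1409 lower with no filter on low counts. Without SUM149 and SUM159 the numbers were 140 in Luminal in place of 111, 220 in Basal A in place of 151 and 1582 in Basal B in place of 3616. Luminal and Basal A kept their lines there. All subtypes shared 1 estimate of the spread, so leaving out Basal B lines can change the counts of the other subtypes. Basal A gave 56 genes in place of 151 without HCC1569 and 70 without MDA-MB-468. Without MCF10A, MCF12A and HBL100, lines of Basal B not derived from a carcinoma, Basal B gave 1569 genes and Basal A 291. Genes higher in Luminal and in Basal A lines numbered 43 (0.689 by independent draws), in Luminal and Basal B 61 (9.34) and in Basal A and Basal B 105 (14.4). Genes lower in both numbered 0, 4 and 0 for the same pairs (0.00746, 1.57 and 0.696 by independent draws). With camera 13, 22 and 18 lists were called up in Luminal, Basal A and Basal B and 6, 3 and 6 down; with an estimated correlation these were 5, 10 and 11 up and 0 down.

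In the 2 Normal lines 3 genes passed. Their SE and p-values rest on the spread that all subtypes share in the fit, and so mostly on lines outside this group. The peptidase gene CPA4 rose by 2.10 ± 0.33 (adjusted p = 0.00203), and the calcium-binding protein gene S100A9 (−2.36 ± 0.40, adjusted p = 0.00613) and SCG5 (−1.79 ± 0.27, adjusted p = 0.00108) fell. CA9 had 4.55 ± 1.05 and did not pass (adjusted p = 0.150). Glycolysis genes were called up (adjusted p = 7.47e-11, but adjusted p = 0.129 with an estimated correlation) and NF-kB genes down (adjusted p = 6.73e-09, but adjusted p = 0.0900 with an estimated correlation), with 0 members past the test in edgeR. Leaving out either line left 0 or 1 gene, and DESeq2 gave 8.

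A further comparison asked whether the response itself differed between subtypes. Between Luminal and Basal B lines 11 genes differed, 4 with a higher and 7 with a lower effect in Luminal lines. CA12, a membrane carbonic anhydrase, differed by −1.32 ± 0.24 (adjusted p = 0.0148): its effect was −0.14 ± 0.18 in Luminal lines and 1.19 ± 0.16 in Basal B lines. The calcium channel gene ITPR1 differed by −1.08 ± 0.20, with effects of 0.13 ± 0.15 and 1.21 ± 0.13, and the trophoblast glycoprotein gene TPBG by −1.21 ± 0.21, with −0.11 ± 0.16 and 1.10 ± 0.13. The sodium-calcium exchanger gene SLC8A1 (−1.92 ± 0.38) and RNF223 (−1.24 ± 0.26) were also lower. The genes with a higher effect in Luminal lines were FGD5 (3.29 ± 0.64), the mucins MUC5AC (2.35 ± 0.43) and MUC5B (1.49 ± 0.31), and the sialyltransferase gene ST6GAL1 (0.98 ± 0.20). Outside the naming rule, because of their low level, and chosen after their values were seen, were ZP1 (−4.25 ± 0.66) and GPR143 (−1.65 ± 0.34). DESeq2 gave 6 genes and limma-voom 7. Leaving out BT20 or HCC1937, Basal A lines in the same fit, gave 7 each. Without SUM149 and SUM159 there were 5, and without MCF10A, MCF12A and HBL100 also 5.

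With all lines and the filter, neither other pair of subtypes gave a gene in edgeR. For Luminal against Basal A the number was 0 (1369 at an unadjusted p under 0.05; 0 with DESeq2 and 0 with limma-voom), and the smallest adjusted p was 0.308 for NUTM2B (1.69 ± 0.35). The number became 2 without HCC1569 and 1 without Sum225CWN. For Basal A against Basal B it was 0 as well (1323 at an unadjusted p under 0.05; 0 with DESeq2 and 0 with limma-voom), with KDR at 3.82 ± 0.76 (adjusted p = 0.266). In edgeR it became 2 with no filter, 2 without HCC1569, 3 without Sum225CWN and 1 without MCF10A, MCF12A and HBL100. Over all 3 subtypes 1 gene, ZP1, passed (adjusted p = 0.0278), but 0 passed without SUM149 and SUM159 or without HCC1937, 8 without Sum225CWN, 24 with no filter, 4 with DESeq2 and 5 with limma-voom. Camera called 1 list higher and 13 lower in Luminal than in Basal A, 1 and 6 in Luminal against Basal B, and 7 and 0 in Basal A against Basal B, and 0 lists for each pair with an estimated correlation. Cholesterol synthesis in Luminal against Basal A was an example (adjusted p = 7.49e-11, but adjusted p = 0.251 with an estimated correlation). In simulated data a 2-fold difference was found for 68.7% of genes between Luminal and Basal B, for 43.3% between Luminal and Basal A and for 50.7% between Basal A and Basal B. These shares hold for the simulated spread between lines, which was smaller than that of the response index.

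The size of the response was summarised per line as the mean log2 ratio of the 10 response index genes. It averaged 1.78 ± 0.80 in Luminal (SD, n = 9), 2.54 ± 0.56 in Basal A (SD, n = 5) and 2.30 ± 1.34 in Basal B (SD, n = 14). The lowest values were 0.47 in SUM1315 and 0.58 in SKBR3, and the highest 4.91 in MCF12A and 4.17 in MCF10A. No pair of subtypes differed by a two-sided exact permutation test: Luminal minus Basal A was −0.76 (95% bootstrap interval −1.41 to −0.09; exact p = 0.0859, adjusted p = 0.258), Luminal minus Basal B −0.52 (−1.38 to 0.29; permutation p = 0.310, adjusted p = 0.465) and Basal A minus Basal B 0.25 (−0.57 to 1.02; permutation p = 0.697, adjusted p = 0.697). The differences from Basal B without SUM149 and SUM159 were −0.28 for Luminal and 0.49 for Basal A (adjusted p = 0.586 for each). The index is a ratio and does not give the starting level. At 20% O2 camera called the index genes lower in Luminal and in Basal A than in Basal B lines (adjusted p = 0.00598 and 0.0199). Neither call held with an estimated correlation (adjusted p = 0.130 and 0.283), and Luminal against Basal A was not called (camera adjusted p = 0.451). Over the 31 lines the index did not follow the 20% O2 level of HIF1A (Pearson r = 0.247, two-sided permutation p = 0.179; Spearman rho = 0.129, p = 0.488), EPAS1 (r = −0.0364, p = 0.844; rho = −0.00887, p = 0.963), ARNT, the partner of both (r = 0.0554, p = 0.766; rho = 0.00161, p = 0.994), or EGLN1 (r = −0.194, p = 0.294; rho = −0.321, p = 0.0804). Adjusted p over these 4 relations ran from 0.589 to 0.844 for r. Without the 2 lines farthest from the median level, r was 0.0432, 0.107, 0.111 and −0.256 for HIF1A, EPAS1, ARNT and EGLN1. Within the 9 Luminal lines EPAS1 had r = −0.746 (exact p = 0.0215, adjusted p = 0.0859; rho = −0.750, exact p = 0.0255), which became −0.518 without the 2 farthest lines (exact p = 0.241). There r was −0.321 for HIF1A (exact p = 0.397), −0.497 for EGLN1 (exact p = 0.179) and 0.339 for ARNT (exact p = 0.371), the last of which became 0.783 without its 2 farthest lines (exact p = 0.00913). Within the 14 Basal B lines r was 0.419 for HIF1A (permutation p = 0.137, adjusted p = 0.536), 0.151 for EPAS1, 0.177 for ARNT and −0.318 for EGLN1. Correlations were computed for subtypes of at least 6 lines, so none was computed within the 5 Basal A lines.

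**Figure D3:**
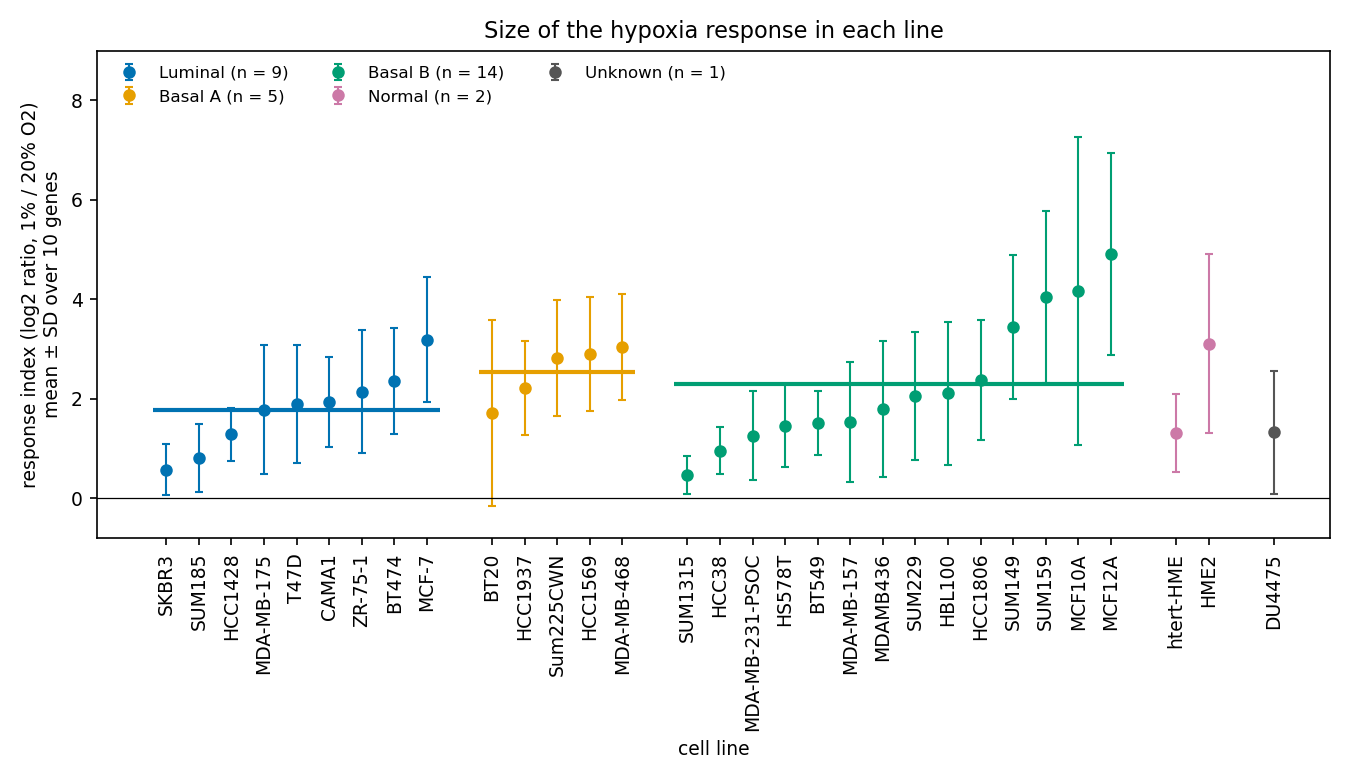
Response index of each line by subtype (points, mean log2 ratio of 1% to 20% O2 over 10 genes, with SD over the genes; horizontal lines, subtype means). The means are 1.78 in Luminal, 2.54 in Basal A and 2.30 in Basal B, and the lines run from 0.47 to 4.91.

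At 20% O2 the subtypes differed in the genes that define them. Luminal lines expressed the estrogen-responsive genes TFF1 (log2 fold change 11.06 ± 0.87 over Basal B, 8.86 ± 1.24 over Basal A), TFF3 (11.08 ± 0.84 and 8.16 ± 1.13) and the progesterone receptor PGR (10.52 ± 0.95 and 10.14 ± 1.52). The mean log2 CPM of PGR was 4.46 ± 4.59 in Luminal (SD, n = 9), −1.30 ± 0.23 in Basal A (SD, n = 5) and −1.80 ± 0.76 in Basal B (SD, n = 14). The luminal transcription factors SPDEF (8.87 ± 0.80) and FOXA1 (6.09 ± 0.69) were higher in Luminal than in Basal B lines, and higher in Basal A than in Basal B by 7.12 ± 0.79 and 4.99 ± 0.70. Of 22 luminal genes 21 were higher in Luminal than in Basal B (adjusted p = 1.27e-16), 8 than in Basal A (adjusted p = 2.32e-13), and 9 were higher and 1 lower in Basal A than in Basal B (adjusted p = 0.00106, but adjusted p = 0.237 with an estimated correlation). Mesenchymal genes were lower in Luminal than in Basal B lines in 23 of 23 cases (adjusted p = 2.73e-15), with the membrane linker MSN at −6.43 ± 0.77, the receptor kinase AXL at −8.93 ± 1.17, ZEB1, a repressor of epithelial genes, at −7.88 ± 0.92 and TGFBI at −8.81 ± 0.98. In Luminal against Basal A 1 was higher and 10 lower (adjusted p = 6.42e-04, but adjusted p = 0.375 with an estimated correlation), and in Basal A against Basal B 12 were lower (adjusted p = 2.96e-13, but adjusted p = 0.111 with an estimated correlation), ZEB1 by −6.03 ± 1.06.

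Basal keratinocyte genes were lower in Luminal than in Basal B lines in 17 of 23 cases (adjusted p = 4.67e-04, but adjusted p = 0.438 with an estimated correlation) and than in Basal A lines in 9 (adjusted p = 3.04e-06, but adjusted p = 0.375 with an estimated correlation). KRT14 differed by −10.27 ± 1.78, KRT5 by −9.05 ± 1.84, S100A2 by −8.51 ± 1.35 and EGFR by −2.77 ± 0.80 between Luminal and Basal B, and KRT5 by −7.56 ± 1.81 and EGFR by −4.54 ± 0.95 between Luminal and Basal A. Between Basal A and Basal B 1 basal gene passed (list adjusted p = 0.925). CA12, which rose at 1% O2 in Basal B, was higher at 20% O2 in Luminal than in Basal B lines by 2.16 ± 0.59 and than in Basal A lines by 7.84 ± 1.20. Among all genes 2745 were higher and 2948 lower in Luminal than in Basal B, 362 and 810 in Luminal against Basal A, and 799 and 477 in Basal A against Basal B. The balance turned to 653 higher and 701 lower in Basal A against Basal B with DESeq2, and to 2158 and 1906 in Luminal against Basal B with limma-voom. The totals without SUM149 and SUM159 were 5072, 1097 and 963 for Luminal against Basal B, Luminal against Basal A and Basal A against Basal B. Limma-voom gave 295 genes for Luminal against Basal A in place of 1172 and 375 for Basal A against Basal B in place of 1276. Leaving out HCC1937 gave 743 for the former pair, and leaving out Sum225CWN gave 531 and MDA-MB-468 801 for the latter.

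**Figure D4:**
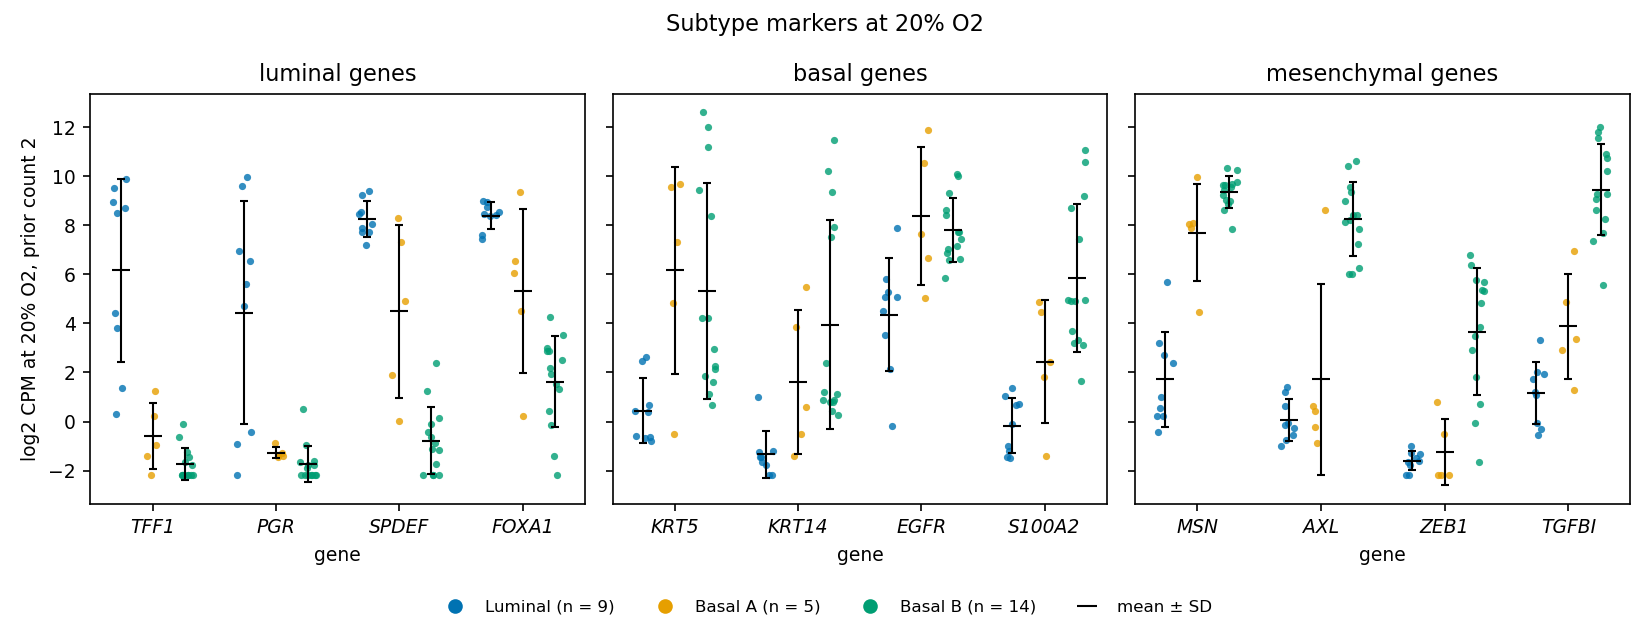
Level at 20% O2 (log2 CPM) of 4 luminal, 4 basal and 4 mesenchymal genes in Luminal (9), Basal A (5) and Basal B (14) lines, with points for lines and bars for mean and SD. PGR averages 4.46 in Luminal and −1.80 in Basal B lines.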

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

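Of the tests below, the comparison of the spread of levels between O2 concentrations, the number of genes set apart between SUM149 and SUM159, the difference of their correlations at 20% and 1% O2, and all models without these 2 lines were chosen only after the results were seen.

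A difference between groups singled out 11 genes whose response differed between Luminal and Basal B lines by the test of the difference itself. The differences in log2 fold change, Luminal minus Basal B, were −4.25 for ZP1, −1.92 for SLC8A1, −1.65 for GPR143, −1.32 for CA12, −1.24 for RNF223, −1.21 for TPBG and −1.08 for ITPR1, and 3.29 for FGD5, 2.35 for MUC5AC, 1.49 for MUC5B and 0.98 for ST6GAL1. In edgeR with all lines 1 of 21 splits, the real one, reached this number of 11, and the highest other split gave 9. A share of 1 in 21 is the smallest that these splits can give and was not adjusted over the contrasts. Chance therefore cannot be firmly excluded. The number was at or under that 9 with DESeq2 (6), with limma-voom (7), without BT20 or HCC1937 (7 each), without MDA-MB-468 (9), without SUM149 and SUM159 (5) and without MCF10A, MCF12A and HBL100 (5), and the splits were not drawn again under these settings. A test for a value far from the others (Dixon) was run within Luminal and within Basal A lines, for the response index, its genes, HIF1A and EPAS1. Of these 26 groups of values 0 had one. Basal B, with more lines than the test allowed, was not tested.

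Luminal minus Basal A gave 0 genes in edgeR (1369 at an unadjusted p under 0.05; 0 with DESeq2 and limma-voom), and 9 in the highest other split. Basal A minus Basal B gave 0 genes in edgeR (1323 at an unadjusted p under 0.05; 0 with DESeq2 and limma-voom), and 13 in the highest other split. A count of 0 is reached by 21 of 21 splits whatever the data, so the splits decide nothing for these contrasts. Over any of the 3 subtypes 1 gene passed, for which chance cannot be excluded, since 10 of 21 splits gave as many and the highest other gave 9. For the effect of O2, chance is argued against for the 4528 genes over all lines (1 of 40 splits, highest other 10). The same holds for the 111 within Luminal (1 of 21, highest other 1) and the 3616 within Basal B (1 of 21, highest other 724). The 16 splits of Basal A were too few for a share under 0.05, with 151 genes for the real one and 5 for the highest other. At 20% O2 the real labels gave 1172 genes for Luminal against Basal A (highest other of 100 splits 205), 5693 for Luminal against Basal B (710) and 1276 for Basal A against Basal B (262). Such subtypes are told apart by genes like these, so larger counts than with shuffled labels were likely from the start. These splits are thus no independent support.

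The size of the response differed between lines, with an SD of the response index of 1.07 over 31 lines. Depth as the main source is argued against, since the index did not follow the log2 ratio of the total counts of the libraries of a line (r = 0.0271, permutation p = 0.885; rho = 0.00323; r = −0.0517 without the 2 farthest lines; upper 95% bound of r squared 0.143). The choice of TMM over size factors is argued against too, since size factors gave 1.02 times the SD. Both scalings assume that most genes do not change, so an effect common to both was not tested. A ceiling for lines that start high would bring lines together at 1% O2, but the SD of the index genes' level was 1.76 times that at 20% O2 (0.745 and 1.31; permutation p = 5.20e-04). Subtype stays open, because the smallest adjusted p of the 3 pairs was 0.258 and their intervals reached beyond 1 log2 unit, so it cannot be told apart from differences between lines within a subtype.

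The SUM149 and SUM159 libraries resembled each other (r = 0.968 at 20% O2 and 0.956 at 1% O2) more than the other library of their own line (r = 0.949 and 0.954), where the median over 465 pairs of lines at 20% O2 was 0.807 and the next highest 0.941. The same cells under both labels are argued against by 15 genes at least 8-fold apart in the same direction at both O2 levels (0.0207 from independent noise), among them KRT14 (186 CPM in SUM149 and 1.19 in SUM159 at 20% O2) and KRT5 (334 and 18.6); an earlier criterion, genes changed within each line's own pair, had come out the other way (26 and 48). A shared response to hypoxia is argued against by the correlation being 0.0113 higher at 20% than at 1% O2. SUM149 libraries that hold mostly RNA of SUM159 cells remain a candidate explanation, since 0 genes of at least 32 CPM in SUM159 were 8-fold or more lower in SUM149 at both O2 levels, against 15 the other way, while HME2 and htert-HME gave 43 and 26 and MCF10A and MCF12A 27 and 34. Lines that are alike by origin also remain open, untested.

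More genes passed in Basal B (3616) than in Luminal lines (111). SUM149 and SUM159 alone are argued against as the source, since Basal B gave 1582 genes without them. The number of lines may account for much of it, because 20 random draws of 9 Basal B lines fitted alone gave from 64 to 1724 genes with a median of 302, a range that holds the 128 of the Luminal lines fitted alone. Those 128 lay below the median of the draws. The draws of 1018, 1360, 1561 and 1724 genes all held both SUM149 and SUM159, but so did the draw of 64. A stronger response in Basal B is the biological explanation, and it stays open, since the response index did not differ between these subtypes by its exact test.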

How the results depend on the processing

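Models without SUM149 and SUM159, those leaving out Basal A lines and the values within subtypes without MCF10A, MCF12A and HBL100 were chosen after the data were seen. The 4528 genes over all lines stayed within 1.5 times under DESeq2 (4358), limma-voom (4357), no filter (3327), size factors (4504), the older quasi-likelihood fit (3930), the models without Normal and Unknown lines (4361), also without MCF10A, MCF12A and HBL100 (3322), or without SUM149 and SUM159 (3314), and with each line left out (3842 to 4659). A minimum of 1.5-fold left 635. Without the line as a block, which pairs the libraries, 111 genes remained over all lines, 5 in Luminal, 4 in Basal A, 75 in Basal B, 0 in Normal and 0 for Luminal minus Basal B.

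Without MCF10A, MCF12A and HBL100 the numbers were 291 in Basal A, 1569 in Basal B, 12 in Normal, 5 for Luminal minus Basal B, 1 for Basal A minus Basal B and 5 for any difference. Basal A and Normal kept their lines there but shared the estimate of the spread with Basal B. Without SUM149 and SUM159 they were 1582 in Basal B, 9 in Normal, 5 for Luminal minus Basal B and 0 for any difference. No filter gave 7 in Normal, 22, 2 and 24 for Luminal minus Basal B, Basal A minus Basal B and any difference. DESeq2 gave 8 in Normal, 6 for Luminal minus Basal B and 4 for any difference, and limma-voom 7 and 5 for these contrasts. Basal B fitted alone gave 2093. At 20% O2 limma-voom gave 295 for Luminal minus Basal A and 375 for Basal A minus Basal B. With an estimated correlation 0 lists were called down, and at 2-fold 13 genes rose in at least 24 lines.

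Leaving out Basal A or Normal lines in turn, while no Luminal or Basal B line was left out singly in these fits, gave 56 (without HCC1569) to 171 genes in Basal A (70 without MDA-MB-468) and 0 to 1 in Normal, where the lone line left was assumed to vary like the others. For the differences it gave 0 to 2 for Luminal minus Basal A (2 without HCC1569, 1 without Sum225CWN), 7 (without BT20 or HCC1937) to 11 for Luminal minus Basal B, 0 to 3 for Basal A minus Basal B (3 without Sum225CWN, 2 without HCC1569) and 0 to 8 for any difference (8 without Sum225CWN, 5 without HCC1569, 0 without HCC1937). At 20% O2 it gave 743 (without HCC1937) to 1334 for Luminal minus Basal A and 531 (without Sum225CWN) to 1185 for Basal A minus Basal B (801 without MDA-MB-468). SCG5 over all lines reversed without Normal and Unknown lines, from −0.09 to 0.39 (adjusted p = 0.0344). At 20% O2 the Luminal minus Basal A difference ran from −5.55 to 1.31 for A2M (without HCC1569), −6.64 to 0.17 for AXL (without HCC1937) and −1.71 to 9.58 for SCGB2A2 (without Sum225CWN), and that of CHI3L1, Basal A minus Basal B, from −3.21 (without HCC1569) to 6.08. Apart from fewer lines or genes tested, and an estimate of the spread that the subtypes share in a fit, the cause of these shifts was not tested.

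Of 7960 values of 199 named genes over all lines under alternatives, 7520 kept direction and side of the threshold, 412 no longer passed, 27 newly passed and 1 reversed. Most of these values come from fits that each left out a single line and so share nearly all their data. The share that stayed therefore says little about the choice of normalization, filter or test. Of 132 values of 11 genes for Luminal minus Basal B, 97 kept both and 35 no longer passed, and of 42 values of 3 genes in Normal these numbers were 33 and 9. Of 175 list values 152 stayed, 19 no longer passed and 4 newly passed. In simulated data 16.4% of 2-fold changes were found in Normal and 71.6% in Basal A, so smaller changes there were mostly not detectable.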

Other observations

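The 4 lists set against the response index below were chosen from 35 after the list tests were seen, though each direction was written down before its correlation was computed.

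At 20% O2 inflammatory and interferon genes also differed between subtypes. Of 34 interferon stimulated genes 22 were lower in Luminal than in Basal A lines (adjusted p = 1.55e-29; adjusted p = 0.00323 with an estimated correlation) and 23 lower than in Basal B lines (adjusted p = 9.73e-09, but adjusted p = 0.130 with an estimated correlation). NF-kB and inflammatory genes were lower in Luminal than in Basal B lines in 19 of 25 cases (adjusted p = 5.08e-09, but adjusted p = 0.108 with an estimated correlation). Of 20 immune evasion genes 7 were lower in Luminal than in Basal A (adjusted p = 1.52e-06; 0.00323 with an estimated correlation), and 1 was higher and 12 lower in Luminal than in Basal B (adjusted p = 5.95e-07; 0.00242 with an estimated correlation). Camera called 3 lists higher and 8 lower in Luminal than in Basal A, 2 and 19 in Luminal against Basal B and 2 and 10 in Basal A against Basal B. With an estimated correlation these were 1 and 2, 1 and 2, and 0 and 0 (smallest adjusted p = 0.111 with an estimated correlation for Basal A against Basal B).

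In the lines outside the 3 subtypes, the response index was 1.33 in DU4475, 1.31 in htert-HME and 3.11 in HME2, against 2.15 ± 1.07 (SD) over the 31 lines.

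A hypothesis was that lists shift in step with the size of the response in a line. The mean log2 ratio of ribosome biogenesis genes fell as the index rose over 31 lines (r = −0.820, adjusted p = 4.00e-05, from 1e-05, the smallest p that 100000 permutations can give; rho = −0.787, adjusted p = 4.00e-05; r = −0.707 without the 2 lines farthest from the list's median). The 2 lines left out were chosen for each list by its own mean log2 ratio. DNA replication genes (r = −0.593, adjusted p = 7.73e-04; rho = −0.483, adjusted p = 0.00888; −0.458 without the 2) and mitochondrially encoded mRNAs (r = −0.407, adjusted p = 0.0231; rho = −0.418, adjusted p = 0.0199; −0.407 without the 2) went the same way, and histone mRNAs the other (r = 0.697, adjusted p = 6.00e-05; rho = 0.519, adjusted p = 0.00628; 0.497 without the 2). Within the 14 Basal B lines r was −0.890, −0.728, −0.759 and 0.928 (adjusted p = 1.60e-04, 0.00492, 4.80e-04 and 4.00e-05), whereas within the 9 Luminal lines it was −0.700 (exact test, adjusted p = 0.145), −0.388, −0.304 and −0.229, so the relations were not shown there and that of histones had the other sign. Without SUM149 and SUM159 r was −0.781, −0.500, −0.443 and 0.650, but rho no longer passed for DNA replication (adjusted p = 0.0556), mitochondrially encoded mRNAs (0.0556) and histones (0.0532). With the 2 lines then farthest from each list's median also left out, r was −0.234 for DNA replication and 0.279 for histones (permutation p = 0.240 and 0.160). Over all lines these relations thus leaned on those lines. Within Basal B without its own 2 farthest lines r stayed at −0.661 and 0.887 (permutation p = 0.0256 and 1.70e-04). The index also went with the SD of the log2 ratios of all genes (r = 0.822), so a general scale of change per line may underlie these relations.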
